A study of Neurospora crassa OR74A with 15 samples.

How the data were processed

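Messenger RNA was purified from mycelia with oligo dT beads, fragmented and copied with random primers, per the labels' protocols. Each of 15 libraries came with a table of FPKM values that the authors deposited, and 1 further table held their pooled FPKM per carbon source. The submitters' processing notes name TopHat 1.2.0, Cufflinks 0.9.3 and Cuffdiff, without saying what each was used for. The genome build and the gene annotation are not given in the sources used here. The 6 tables of the new source are gene-level, and the 9 of the earlier source are transcript-level and also hold, per the file headers, a coverage signal and a transcript length.

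The table kinds name genes differently: 9733 loci were joined by identical coordinates, of which 863 carried different identifiers, and 552 of 9423 shared identifiers lay at loci that did not overlap. The identifiers of the gene-level tables were kept. FPKM of the transcripts of a locus were summed for the 164 loci with more than 1 transcript. Positions are those of the deposited tables, whose starts count from 0 (2033 loci have a length equal to end minus start) and are printed counting from 1. Symbols came from the RefSeq gene table of assembly NC12, in which 9215 locus identifiers were found and 1113 had a symbol of their own. Near-identical paralogs may share reads in these values, and the tables do not show how such reads were divided.

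FPKM values are not counts, and no whole reads could be recovered. Where the tables give coverage, its ratio to FPKM implies 60.4, 386 and 355 megabases of mapped sequence for Avicel replicates 1 to 3, 402, 1014 and 1052 without carbon, and 61.9, 238 and 209 on sucrose. The depth of the 6 new libraries is unknown. The first percentile of nonzero values, as FPKM times kilobases, lay at 7.43, 6.55 and 7.08 in Avicel replicate 1, sucrose replicate 1 and the xylan library and at 0.696 to 2.73 in the others, so low values are least precise in these 3, and an exact 0 is reported only as listed at 0.

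Genes with a mean of at least 1 FPKM over the 14 libraries of replicated groups were tested (8700 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) over all 5 replicated groups with a moderated variance trend (9 residual and 2.94 prior degrees of freedom), since groups of 2 or 3 libraries estimate the spread poorly alone. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The 9 comparisons and their groups, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. All tests are two-sided.

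The 11 gene lists were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over lists within a comparison. Another 5 lists defined by words of an annotation (ribosomal proteins, proteasome, aminoacyl-tRNA synthetases, heat shock proteins, sugar transporters) were not run, because the gene table used here holds no such descriptions. Genes named in the text are up to 4 called members of each list with the largest absolute change, all galacturonate-use and transcription factor genes where needed, and the 5 largest increases and 5 largest decreases among called genes with a symbol whose groups do not overlap. List members that were not called may be named with values only. For the xylan library, up to 4 members per list with the largest difference were eligible, among genes of at least 10 FPKM in it or in the compared group. Values of the same genes in further groups are given beside them without a test.

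The code was tested on simulated data with 200 changed genes among 8700. For Avicel against no carbon it called 76% of genes changed by 1.5 log2 units and 91% of those changed by 3, with 4 false calls among 8500 unchanged genes. For orange peel powder against no carbon the shares were 62% and 94%, with 8 false calls. The simulated noise was normal, independent between genes and of equal spread in all groups. These values therefore do not show how the code behaves where groups differ in spread or genes vary together. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, upper-quartile and quantile scaling, limma without the trend and with robust moderation, other thresholds, the 2 groups of a comparison alone, the replicate number as a block, and leaving out each replicate. Added after the data were seen were joining by identifier, leaving out Avicel replicate 1 and sucrose replicate 1, setting values under 10 FPKM to 10, and the block for the shared genes.

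The authors' pooled FPKM matched the means of the deposited libraries within 1% for 99.986% of genes at 20 FPKM or more on pectin and for 6.712% on Avicel. Within 1.5-fold the share on Avicel was 99.026%. Called genes found in that table had the same direction there, except 1 gene in orange peel powder against sucrose. Figures were drawn with matplotlib 3.10.9, and tables were built with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.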

Results

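RNA was sequenced from mycelia of a wild-type strain of the filamentous fungus Neurospora crassa, which grows on dead plant material and secretes enzymes against each polysaccharide of the plant cell wall. Cultures were grown for 16 h on 2% sucrose, washed, and moved for 4 h to fresh medium with a new carbon source or with none. The 15 libraries formed 6 groups: 3 libraries with 1% pectin, 2 with 1% orange peel powder (a pectin-rich plant material), 1 with 2% xylan (the main hemicellulose of hardwoods and grasses), 3 with 2% Avicel (microcrystalline cellulose), 3 with 2% sucrose and 3 without carbon. The design text calls the replicates biological. The labels assign the 6 libraries on pectin, orange peel powder and xylan to this study and the 9 others to an earlier one, so carbon source and study of origin cannot be told apart wherever these sets are compared. Values are FPKM, fragments scaled by transcript length and library size. Sequencing depth could be derived for the 9 earlier libraries only: 60.4 megabases of mapped sequence for Avicel replicate 1, 61.9 for sucrose replicate 1, and 209 to 1052 for the other libraries. Between 718 and 2341 of 9733 genes were listed at 0 in a library, the most in sucrose replicate 1.

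Across 8700 genes, sucrose separated from all other carbon conditions, and pectin and orange peel powder lay together. The first component held 56.85% of the variance and the second 14.97%. The 3 sucrose libraries scored from -146.98 to -132.65 on the first component, while no carbon, pectin, orange peel powder and Avicel libraries scored from 6.27 to 72.86 and the xylan library scored -23.92. Pearson's r across genes, which are not independent replicates, was 0.978 to 0.984 between pectin libraries, 0.992 between the orange peel powder libraries, 0.949 to 0.977 without carbon, 0.957 to 0.989 on sucrose and 0.904 to 0.99 on Avicel. Avicel replicate 1, the shallowest of the 9 libraries of known depth, scored 38.41 on the first component and 7.02 on the second, away from Avicel replicates 2 and 3.

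**Figure D1:**
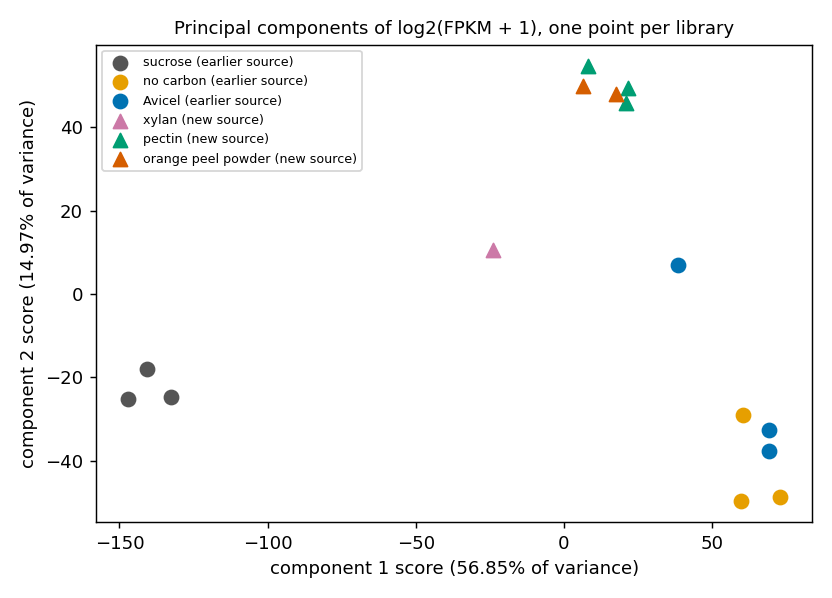
Scores of the 15 libraries on the first (x axis, 56.85% of variance) and second (y axis, 14.97%) principal components of log2(FPKM + 1) over 8700 genes, with 1 point per library, circles for the earlier source and triangles for the new source. The sucrose libraries lie at -146.98 to -132.65 on the x axis, and all libraries of the new source lie above 0 on the y axis.

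The first comparison asks which genes respond to cellulose when starvation is the reference, with all libraries from the earlier source. Cellulase genes were higher by orders of magnitude on Avicel. The cellobiohydrolase gene cbh-1 (NCU07340, contig 10.4, positions 4311049 to 4313881) reached 125864 ± 53336 FPKM (SD, n = 3) against 114 ± 9.76 without carbon (n = 3). The endoglucanase gene gh5-1 (NCU00762) reached 48208 ± 18057 against 13.4 ± 2.71, and the xylanase genes gh10-1 (NCU05924) and gh11-2 (NCU07225) reached 19787 ± 9682 and 104663 ± 21117 against 5.80 ± 0.907 and 163 ± 53.3. The transcription factor gene clr-2 (NCU08042, contig 10.4, positions 4001190 to 4004631), a known activator of cellulase genes, was at 1311 ± 200 against 11.8 ± 6.94. The log2 fold changes of these genes were 10.02, 11.66, 11.41, 9.36 and 6.80.

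Of 24 measured cellulose-degradation genes, 23 were higher on Avicel (23 higher and 1 lower when adjusted over the list alone), and gh61-10 did not pass the test over all genes (adjusted p = 0.114). Of 16 xylan-degradation genes, 14 were higher (15 when adjusted over the list alone), among them NCU05159 (32885 ± 4291 against 134 ± 41.5) and NCU04870 (7120 ± 2162 against 5.87 ± 2.17). Both lists moved together, with adjusted p = 0.00117 and 0.000283 with an estimated correlation. Of 15 pectin-degradation genes, 8 were higher (9 when adjusted over the list alone; adjusted p = 0.00968 with an estimated correlation), such as NCU08176, with 1637 ± 695 against 18.3 ± 2.76. NCU07326 of the same list varied widely between the Avicel libraries (10197 ± 12458, against 55.6 ± 9.55 without carbon). Of 5 genes for the uptake and breakdown of galacturonic acid, the sugar acid of pectin, NCU01906 alone was higher (837 ± 348 against 314 ± 120), a call that was lost without Avicel replicate 2 or 3 or no carbon replicate 1 or 2 (adjusted p of 0.0573, 0.0576, 0.0576 and 0.0548), and the list did not pass (adjusted p = 0.703).

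Of 9 pentose-use genes, 4 were higher by either adjustment, that is, also when adjusted over the list alone (adjusted p = 0.0362 with an estimated correlation), led by xr (NCU08384) at 27565 ± 16477 against 92.0 ± 18.8. Of 9 transcription factor genes, clr-1, clr-2, xlr-1 and vib-1 were higher, by all-gene adjustment and when adjusted over the list alone (adjusted p = 0.00283 with an estimated correlation). The vib-1 gene, for example, was at 1341 ± 147 against 263 ± 98.3, while cre-1, the carbon repression factor, was at 318 ± 331 against 245 ± 159 (adjusted p = 0.966). All 6 genes of protein folding in the endoplasmic reticulum were higher (6 when adjusted over the list alone; adjusted p = 0.00968 with an estimated correlation), including the chaperone gene grp78 (NCU03982, 13687 ± 2110 against 1853 ± 278). Of 7 markers of conidia and aerial hyphae, 0 were called over all genes and 5 were lower when adjusted over the list alone. The list passed with the preset correlation (adjusted p = 0.00632) and did not with an estimated one (adjusted p = 0.177 with an estimated correlation). The isocitrate lyase gene acu-3 was lower, at 224 ± 71.1 against 1172 ± 608. In all, limma called 554 of 8700 genes, 351 higher and 203 lower on Avicel. With only these 6 libraries in the fit the count was 332.

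**Figure D2:**
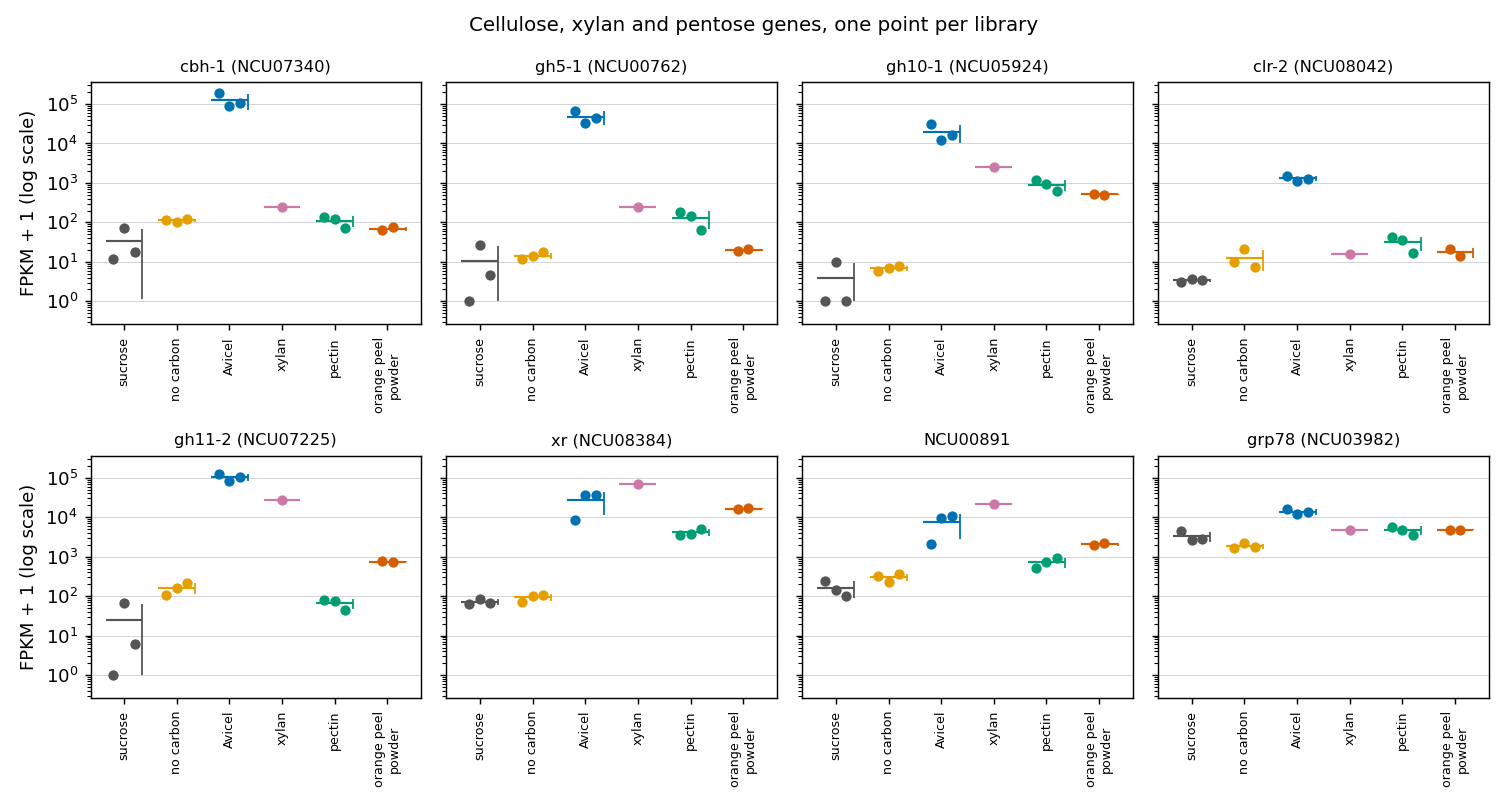
FPKM + 1 on a log axis for 8 genes of cellulose, xylan and pentose use and protein folding, with 1 point per library in the 6 groups, horizontal lines at group means and vertical lines for 1 SD where a group has more than 1 library. On Avicel cbh-1 averages 125864 FPKM against 114 without carbon, while xr is highest in the xylan library, at 70613.

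Pectin was compared with no carbon to find the genes that respond to pectin. Genes that break down pectin and its main sugar acid were higher on pectin. The polygalacturonase gene gh28-2 (NCU06961, contig 10.4, positions 4670149 to 4671713) reached 37411 ± 4701 FPKM (SD, n = 3) against 565 ± 197 without carbon (n = 3), and the lyase genes NCU06326 and NCU08176 reached 12852 ± 1714 and 8939 ± 2115 against 29.3 ± 7.40 and 18.3 ± 2.76. NCU09533 (contig 10.5, positions 4497262 to 4498786), which encodes the reductase of the first step of galacturonic acid breakdown, was at 26319 ± 1688 against 275 ± 146, and the next enzyme genes NCU07064 and NCU09532 were at 9177 ± 1586 and 17591 ± 1280 against 197 ± 53.0 and 340 ± 161. The log2 fold changes of NCU09533, NCU07064 and NCU09532 were 6.73, 5.55 and 5.79.

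All 15 measured pectin-degradation genes were higher on pectin, with 15 also when adjusted over the list alone (adjusted p = 0.00503 with an estimated correlation), and NCU00852 of the list lay below the expression filter. All 5 galacturonate-use genes were higher by both adjustments, with 5 when adjusted over the list alone (adjusted p = 0.00800 with an estimated correlation), including the transporter gene NCU00988, at 6674 ± 1008 against 1140 ± 74.9. Without Avicel replicate 1 and sucrose replicate 1 the galacturonate-use list no longer passed that test (adjusted p = 0.0957 with an estimated correlation), nor did the xylan-degradation list (adjusted p = 0.0766 with an estimated correlation). Neither library is in this comparison, so the fold changes were the same in that fit, and only the estimates of spread and correlation differed. The NCU00988 call was lost with a pseudocount of 0.1 (limma adjusted p = 0.0581), with a log2 fold change of 2.54. Of 16 xylan-degradation genes, 12 were higher, also when adjusted over the list alone (adjusted p = 0.00800 with an estimated correlation), such as NCU09775 (2859 ± 404 against 4.19 ± 1.02) and gh11-1 (1867 ± 391 against 22.7 ± 16.2). The xylanase gene gh11-2 was at 65.4 ± 20.1 against 163 ± 53.3 (adjusted p = 0.361). Of 24 cellulose-degradation genes, 8 were higher and 1 was lower, by both adjustments (8 and 1 when adjusted over the list alone), and 11 were higher and 5 lower without Avicel replicate 1 and sucrose replicate 1. The list passed with the preset correlation (adjusted p = 0.0350) and not otherwise (adjusted p = 0.488 with an estimated correlation). The gene with the largest rise in it, gh6-3, was at 2348 ± 1270 against 99.5 ± 6.77, while cbh-1 was at 109 ± 34.2 on pectin and 114 ± 9.76 without carbon.

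Of 9 pentose-use genes, 4 were higher on pectin, as when adjusted over the list alone (adjusted p = 0.0903 with an estimated correlation), including the arabinitol dehydrogenase gene NCU00643 (7134 ± 2398 against 177 ± 51.9). Of the 9 transcription factor genes, 3 were higher, including vib-1 (935 ± 17.4 against 263 ± 98.3) and clr-2, with 3 also when adjusted over the list alone (adjusted p = 0.0755 with an estimated correlation). For clr-2 (30.3 ± 12.6 against 11.8 ± 6.94) the call was lost without pectin replicate 1 or 2 or no carbon replicate 1 or 3 (adjusted p of 0.0793, 0.0676, 0.0619 and 0.0855). The starch and sucrose enzyme genes gla-1 and inv were higher (12220 ± 5535 against 786 ± 338, and 7903 ± 2492 against 749 ± 565). Of 6 folding genes, 2 were higher, as when adjusted over the list alone (adjusted p = 0.130 with an estimated correlation). These calls, of grp78 and NCU09265, were lost under quantile normalization (log2 fold changes of 0.78 and 0.82). Conidiation markers were lower on pectin: 6 of 7 over all genes and 7 when adjusted over the list alone (adjusted p = 0.0928 with an estimated correlation). The hydrophobin gene eas (NCU08457, contig 10.2, positions 3571946 to 3572797) was at 5157 ± 2754 against 116679 ± 77851, and con-10 was at 142 ± 62.7 against 1942 ± 593. The mating genes ccg-4 and matA-1 were also lower (22.5 ± 4.80 against 1335 ± 272, and 10.3 ± 3.77 against 194 ± 41.0). In all, 1848 genes were called, 902 higher and 946 lower on pectin. Every pectin library came from the new source and every no-carbon library from the earlier one, so source and carbon source cannot be told apart for these genes.

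**Figure D3:**
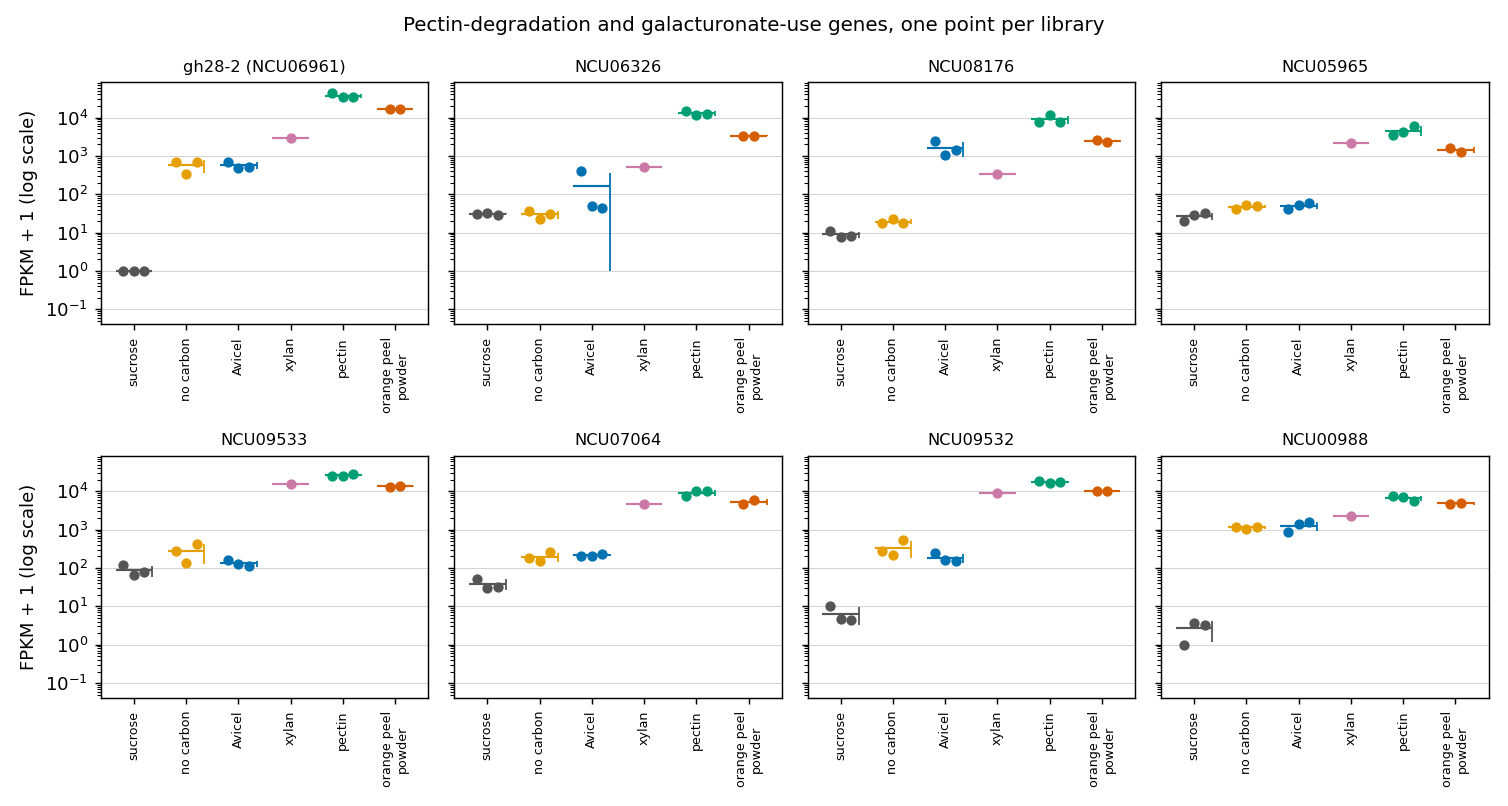
FPKM + 1 on a log axis for 4 pectin-degradation and 4 galacturonate-use genes, with 1 point per library in the 6 groups, horizontal lines at group means and vertical lines for 1 SD where a group has more than 1 library. NCU09533 averages 26319 FPKM on pectin and 13439 on orange peel powder, is at 15461 in the xylan library, and averages 130 on Avicel, 275 without carbon and 86.6 on sucrose.

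Orange peel powder was compared with no carbon to see the response to a whole pectin-rich plant material. Genes of pectin, galacturonic acid, xylan and pentose use were higher on orange peel powder. gh28-2 was at 16910 ± 264 FPKM (SD, n = 2) against 565 ± 197 without carbon (n = 3), NCU09533 at 13439 ± 715 against 275 ± 146, and the xylose reductase gene xr at 16576 ± 329 against 92.0 ± 18.8. The xylanase gene gh11-1 was at 4615 ± 966 against 22.7 ± 16.2, and the invertase gene inv was at 13869 ± 990 against 749 ± 565. All 15 pectin-degradation genes (15 when adjusted over the list alone) and all 5 galacturonate-use genes (5 when adjusted over the list alone) were higher, as were 14 of 16 xylan-degradation genes (15 when adjusted over the list alone) and 7 of 9 pentose-use genes (7 when adjusted over the list alone). The list tests gave adjusted p of 0.00384, 0.00930, 0.00384 and 0.0254 with an estimated correlation. Without Avicel replicate 1 and sucrose replicate 1 the galacturonate-use and pentose-use lists no longer passed (adjusted p of 0.0811 and 0.0590 with an estimated correlation). Here too neither library is in the comparison, and the fold changes were the same. The galacturonate-use call of NCU00988 was lost with a pseudocount of 0.1 (limma adjusted p = 0.163, log2 fold change 2.09).

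Cellulose-degradation genes again went both ways, with 8 higher and 1 lower of 24 (9 and 1 when adjusted over the list alone; adjusted p = 0.496 with an estimated correlation), and 11 higher and 5 lower without Avicel replicate 1 and sucrose replicate 1. Of the transcription factor genes vib-1 alone was called, at 760 ± 17.3 against 263 ± 98.3, with 1 when adjusted over the list alone, and clr-2 was at 16.6 ± 4.89 against 11.8 ± 6.94 (adjusted p = 0.343). Of 6 folding genes, 3 were higher, also when adjusted over the list alone (adjusted p = 0.170 with an estimated correlation). The calls of grp78 and NCU09265 among them were lost under quantile normalization (log2 fold changes of 0.98 and 0.96). Of 7 conidiation markers, 6 were lower (7 when adjusted over the list alone; adjusted p = 0.0738 with an estimated correlation), led by eas at 855 ± 51.5 against 116679 ± 77851. In all, 1838 genes were called, 903 higher and 935 lower, and 718 genes were higher than without carbon both on orange peel powder and on pectin. Without orange peel powder replicate 1 the count was 807, with the remaining library assumed to vary like the other groups. Source and carbon source cannot be told apart here either.

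**Figure D4:**
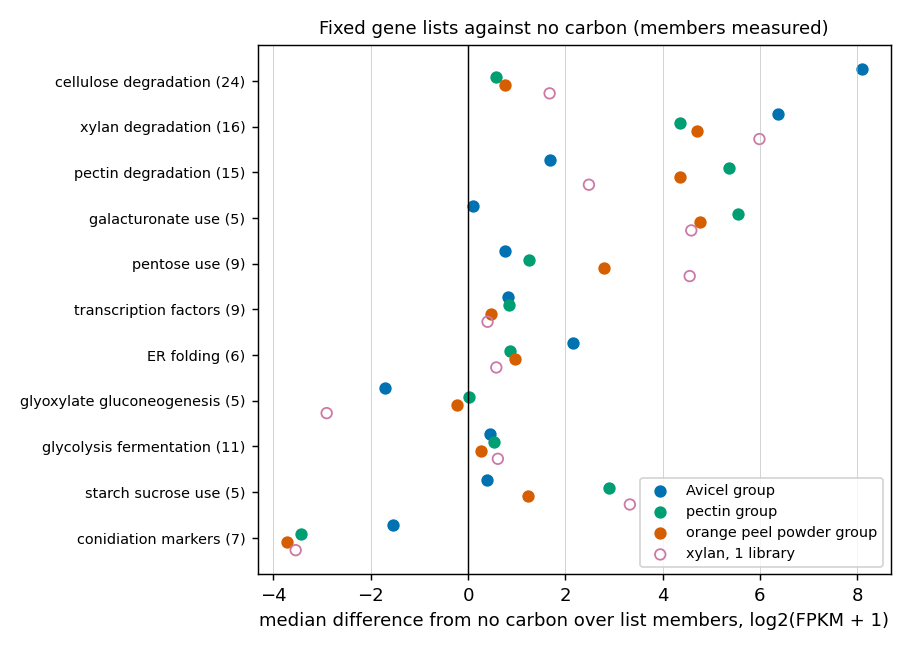
Median difference from no carbon in log2(FPKM + 1) (x axis) over the members of 11 gene lists (y axis, with the number measured), with filled points for the Avicel, pectin and orange peel powder groups and open points for the xylan library. The cellulose list lies at 8.09 on Avicel and at 0.57 on pectin, and the galacturonate list at 0.11 on Avicel and at 5.55 on pectin; the Avicel medians of the glycolysis and starch lists and the pectin median of the glyoxylate list changed sign under quantile normalization.

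The direct comparison of pectin with Avicel asks which genes separate the responses to these polysaccharides. Cellulase genes were lower and galacturonic acid genes higher on pectin. cbh-1 was at 109 ± 34.2 FPKM on pectin (SD, n = 3) and 125864 ± 53336 on Avicel (n = 3), gh6-2 at 47.7 ± 10.3 and 89949 ± 51730, and clr-2 at 30.3 ± 12.6 and 1311 ± 200. NCU09533 was at 26319 ± 1688 on pectin and 130 ± 23.3 on Avicel, and gh28-2 at 37411 ± 4701 and 564 ± 119. Of 24 cellulose-degradation genes, 21 were lower on pectin (21 when adjusted over the list alone), while 14 of 15 pectin-degradation genes were higher and 1 was lower (14 and 1 when adjusted over the list alone). All 5 galacturonate-use genes were higher (5 when adjusted over the list alone). Each of these 3 lists had adjusted p = 0.0101 with an estimated correlation. Without Avicel replicate 1 and sucrose replicate 1 the cellulose-degradation and galacturonate-use lists no longer passed that test (adjusted p of 0.0812 and 0.0987 with an estimated correlation). With a pseudocount of 0.1 the galacturonate-use call of NCU00988 was lost (limma adjusted p = 0.0791, log2 fold change 2.43).

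The xylan-degradation list was divided, with gh11-2 (65.4 ± 20.1 on pectin, 104663 ± 21117 on Avicel) among 9 lower genes and NCU09775 (2859 ± 404 and 97.4 ± 146) among 4 higher ones (9 and 4 when adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). Pentose-use genes were divided as well, 3 higher and 4 lower (3 and 4 when adjusted over the list alone; adjusted p = 0.951 for the list). Of 6 folding genes, 4 were lower, also when adjusted over the list alone (adjusted p = 0.141 with an estimated correlation), and grp78 was at 4716 ± 1113 on pectin and 13687 ± 2110 on Avicel. Of 7 conidiation markers, 3 were lower on pectin, also when adjusted over the list alone (adjusted p = 0.207 with an estimated correlation). Among these, the eas call was lost without pectin replicate 3 or Avicel replicate 1 (limma adjusted p of 0.0930 and 0.0520). The ccg-1 call was lost without pectin replicate 3 or Avicel replicate 2 or 3 (0.0904, 0.0733 and 0.0713) and under quantile normalization (0.0675). In all, 1385 genes were called, 789 higher and 596 lower on pectin. The libraries of each group came from a different source, so source and carbon source cannot be told apart.

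Genes higher than without carbon were then matched between pectin and Avicel. On both polysaccharides 158 genes were higher than without carbon, including 8 of the 24 cellulose-degradation, 10 of the 16 xylan-degradation and 8 of the 15 pectin-degradation genes. On pectin 585 genes were higher than without carbon and than on Avicel, 14 of them in the pectin-degradation list and 5 in the galacturonate-use list. On Avicel 179 genes were higher than without carbon and than on pectin, 21 of them in the cellulose-degradation list and 9 in the xylan-degradation list. Independent lists of 902 and 351 genes among 8700 would share 36.4. Unchanged groups simulated against the same controls shared 0 in each of 100 simulations, but with no real effects few genes are called at all, so this value is no measure for lists of that length. Lower than without carbon on both were 111 genes, against 22.1 for independent lists of 946 and 203. Dividing the 3 no-carbon libraries between the comparisons would leave 1 of them with a single control, so it was not done, and part of the excess over independent lists may come from the shared controls. The pectin libraries came from another source than the Avicel and no-carbon libraries, so source and carbon source cannot be told apart for the pectin list.

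Orange peel powder and pectin, both from the new source, were compared to see how the plant material differs from the purified polysaccharide. Few genes were called, which does not show that few genes differed. The values of the 2 groups did not overlap for 3558 of 8700 genes, where 20% of genes would be apart by chance. Before adjustment 886 genes had a limma p below 0.05. The sterol synthesis gene erg-4 was higher on orange peel powder (6139 ± 329 FPKM, SD, n = 2, against 768 ± 119 on pectin, n = 3), as was ci-1 (1246 ± 116 against 153 ± 2.46). The pectin-degradation genes NCU08176, NCU00972 and NCU05965 were lower (2448 ± 131 against 8939 ± 2115, 435 ± 3.84 against 2298 ± 864, and 1445 ± 274 against 4587 ± 1349). Of 15 pectin-degradation genes these 3 were called over all genes and 9 were lower when adjusted over the list alone (adjusted p = 0.0284 with an estimated correlation). In the xylan-degradation list 1 gene was higher over all genes and 6 when adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). The 1 call, of NCU01900, was lost without pectin replicate 1, 2 or 3 (limma adjusted p of 0.135, 0.120 and 0.0812). It was lost as well without orange peel powder replicate 1 or 2, which leaves 1 library in that group (log2 fold changes of 2.88 and 2.80). It was also lost with the replicate number as a block (limma adjusted p = 0.0784). No galacturonate-use gene was called by either adjustment, that is, 0 over all genes and 0 when adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). NCU09533, for example, was at 13439 ± 715 on orange peel powder and 26319 ± 1688 on pectin (adjusted p = 0.400).

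In all, limma called 27 genes between orange peel powder and pectin, 13 higher and 14 lower on orange peel powder. The count was 160 with only these 5 libraries in the fit, 161 without Avicel replicate 1 and sucrose replicate 1, 13 and 7 without pectin replicate 1 and 2, and 4 and 5 without orange peel powder replicate 1 and 2. NCU08176, NCU00972 and NCU05965 were not called without orange peel powder replicate 1 (adjusted p of 0.315, 0.263 and 0.194) or replicate 2 (adjusted p of 0.288, 0.182 and 0.340), nor without pectin replicate 2 (adjusted p of 0.106, 0.0646 and 0.0711). NCU08176 and NCU00972 were also lost without pectin replicate 1 (adjusted p of 0.0835 and 0.0765), and NCU08176 and NCU05965 without pectin replicate 3 (adjusted p of 0.0527 and 0.0537). With the replicate number as a block the NCU08176 call was lost too (limma adjusted p = 0.0582). The erg-4 and ci-1 genes were called in each fit without 1 of these 5 libraries.

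Sucrose, the carbon source of the preceding culture, was set against each other condition. Conidiation genes and some genes of polysaccharide use were higher in starved mycelia than on sucrose. Without carbon eas was at 116679 ± 77851 FPKM (SD, n = 3) against 202 ± 168 on sucrose (n = 3), the xylanase regulator gene xlr-1 at 334 ± 11.9 against 8.79 ± 2.95, and the glucoamylase gene gla-1 at 786 ± 338 against 55.6 ± 13.3. gh28-2 was listed at 0 in all 3 sucrose libraries and at 684, 337 and 675 FPKM without carbon. Several glycolysis genes were lower without carbon, such as the pyruvate kinase gene ace-8 (1230 ± 261 against 9755 ± 834) and emp-3 (501 ± 158 against 2279 ± 271). Also lower were ilv-2, at 71.0 ± 7.89 against 15993 ± 3487, and arg-3, at 15.9 ± 6.16 against 1843 ± 242.

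Without carbon all 7 conidiation markers were higher than on sucrose (7 when adjusted over the list alone; adjusted p = 0.198 with an estimated correlation), as were 5 of 5 galacturonate-use genes (5 when adjusted over the list alone; adjusted p = 0.198 with an estimated correlation) and 13 of 16 xylan-degradation genes (14 when adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). The cellulose-degradation and pectin-degradation lists went both ways, with 15 higher and 2 lower of 24 (15 and 2 when adjusted over the list alone; adjusted p = 0.0543 for the list) and 9 higher and 2 lower of 15 (10 and 2 when adjusted over the list alone; adjusted p = 0.0628 for the list). Of 11 glycolysis and fermentation genes 8 were lower (8 when adjusted over the list alone; adjusted p = 0.269 with an estimated correlation). Of the transcription factor genes 6 were higher and 1 was lower (7 and 1 when adjusted over the list alone; adjusted p = 0.0685 for the list). The transcription factor gene clr-2 was higher (11.8 ± 6.94 against 2.43 ± 0.306) but had a log2 fold change of -0.40 under quantile normalization. The lower call, of cre-1, was lost under upper-quartile scaling and quantile normalization (limma adjusted p of 0.0874 and 0.0774). It was also lost without no carbon replicate 1 or 3 (0.109 and 0.183) and without sucrose replicate 1, 2 or 3 (0.0839, 0.0822 and 0.107). In all, 4547 genes were called, 2977 higher and 1570 lower without carbon.

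Avicel, pectin and orange peel powder each differed from sucrose in a similar number of genes. Against sucrose limma called 4232 genes on Avicel (2632 higher, 1600 lower), 3552 on pectin (2317 and 1235) and 3497 on orange peel powder (2212 and 1285). On Avicel all 24 cellulose-degradation genes were higher (24 when adjusted over the list alone; adjusted p = 0.0676 with an estimated correlation), with cbh-1 at 125864 ± 53336 against 32.7 ± 32.6 FPKM (SD, n = 3 each). The pectin-degradation list was higher in all 15 genes on pectin (15 when adjusted over the list alone; adjusted p = 0.0154 with an estimated correlation) and on orange peel powder (15 when adjusted over the list alone; adjusted p = 0.0203 with an estimated correlation). The galacturonate-use gene NCU09532 was at 17591 ± 1280 on pectin (n = 3) and 10180 ± 14.6 on orange peel powder (n = 2) against 5.35 ± 3.15 on sucrose. The nitrogen assimilation gene am, which encodes glutamate dehydrogenase, was lower on pectin and on orange peel powder (249 ± 71.9 and 318 ± 13.8 against 17347 ± 2189), and ace-8 was lower on Avicel, pectin and orange peel powder (1750 ± 609, 1777 ± 374 and 1456 ± 103 against 9755 ± 834).

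Relative to sucrose, the scaling of the libraries changed the balance of higher and lower genes. With values as deposited the median log2 fold change of all genes was 0.38 without carbon, 0.24 on Avicel, 0.18 on pectin and 0.21 on orange peel powder. After upper-quartile scaling these medians were 0.66, 0.47, 0.39 and 0.45, and after quantile normalization they were -0.05, -0.07, -0.18 and -0.18. The share of called genes that were higher was 65.5%, 62.2%, 65.2% and 63.3% as deposited, and after quantile normalization it was 50.4%, 48.4%, 45.6% and 44.9%. These medians do not measure how far scaling moves a single gene. Under quantile normalization the glycolysis gene fba was no longer called lower on Avicel (log2 fold change -0.27). The glycolysis gene emp-7 lost its lower call without carbon (-0.50), on Avicel (-1.02) and on orange peel powder (-0.03). For pectin and orange peel powder, source and carbon source cannot be told apart.

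The xylan library has no replicate, so its differences carry no test. Among genes of xylan and pentose use, several were higher in it than in any other library, including xr, NCU00891, NCU01900 and gh3-8. Several xylanase genes were instead higher on Avicel. NCU01900 and gh3-8 of the xylan-degradation list were at 17073 and 2689 FPKM, against at most 13407 and 592 in any other library. The xylose reductase gene xr was at 70613 FPKM in this library, against group means of 27565 on Avicel, 16576 on orange peel powder, 4153 on pectin and 92.0 without carbon. The xylitol dehydrogenase gene NCU00891 was at 21814, against means of 7457 on Avicel and 727 on pectin, and the xylanase gene gh10-2 was at 57020.5, close to the 53692 of Avicel replicate 3 (38118 ± 22515 on Avicel and 1323 ± 117 on pectin). The other xylanase genes gh11-2 and gh11-1 were at 26982 and 379, against means of 104663 and 5357 on Avicel. The galacturonic acid reductase gene NCU09533 was at 15461, against 26319 on pectin and 130 on Avicel, while cbh-1 was at 246, against 125864 on Avicel. clr-2 was at 14.5, against 1311 on Avicel.

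As list medians of log2(FPKM + 1), the xylan library lay above the no-carbon mean by 5.99 over 16 xylan-degradation genes, 4.59 over 5 galacturonate-use genes and 4.56 over 9 pentose-use genes, each at percentile 100 of 10000 random lists of equal size and expression. The percentile was not particular to these lists. The starch and sucrose (3.33), pectin-degradation (2.49) and cellulose-degradation (1.68) lists were at percentile 100 as well. The xylan-degradation difference was 6.63 with a pseudocount of 0.1. Against no carbon the conidiation markers had a median of -3.54 and the 5 glyoxylate and gluconeogenesis genes one of -2.91, each at percentile 0. The isocitrate lyase gene acu-3 of the glyoxylate cycle was at 76.2 FPKM, against 1172 ± 608 without carbon. Against the pectin mean the pectin-degradation list had a median of -2.61 and the xylan-degradation list one of 2.52, and against the Avicel mean the cellulose-degradation list had one of -6.70. The xylan-degradation list had a median of 0.10 against the Avicel mean, with 7 genes above 1 and 6 below -1, and it changed sign under upper-quartile scaling. The percentiles describe these libraries only, and the depth of the xylan library is unknown, with 1871 genes listed at 0.

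**Figure D5:**
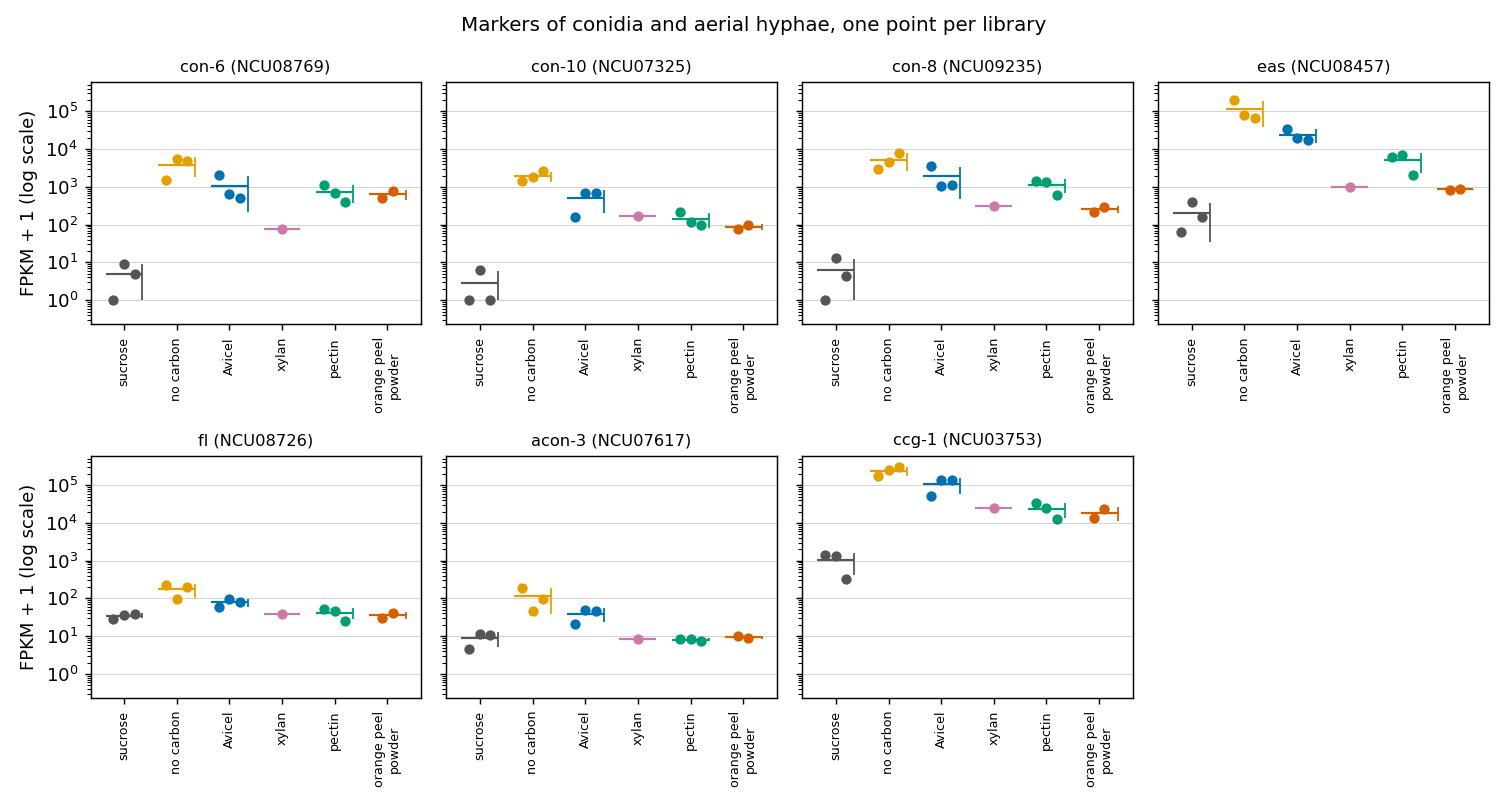
FPKM + 1 on a log axis for 7 markers of conidia and aerial hyphae, with 1 point per library in the 6 groups, horizontal lines at group means and vertical lines for 1 SD where a group has more than 1 library. The hydrophobin gene eas averages 116679 FPKM without carbon, 24105 on Avicel, 5157 on pectin, 855 on orange peel powder and 202 on sucrose.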

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

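The settings added after the results were seen were the join by identifier, the fits without Avicel replicate 1 and sucrose replicate 1, the floor of 10 FPKM and the block for the shared genes. With a log2 threshold of 2 in place of 1, 238 genes were called between Avicel and no carbon, 2340 between Avicel and sucrose, 2685 between no carbon and sucrose, 667 and 1691 for pectin against no carbon and sucrose, 748 and 1653 for orange peel powder against the same, 521 between pectin and Avicel and 14 between orange peel powder and pectin. With the adjusted p alone, 851 genes were called between Avicel and no carbon, 3102 for pectin and 2774 for orange peel powder against no carbon, and 2424 between pectin and Avicel. With only the compared groups in the fit the counts were 332 between Avicel and no carbon and 160 between orange peel powder and pectin. Orange peel powder against pectin, called for 27 genes, moved the most: to 15 with the replicate number as a block, 161 without Avicel replicate 1 and sucrose replicate 1, 51 with values under 10 FPKM set to 10, and 4 to 18 when 1 replicate was left out. Orange peel powder against no carbon gave 807 to 1862 genes when 1 replicate was left out. Libraries outside a comparison do not enter its fold changes. The counts of 332 and 160 with only the compared groups therefore moved through the estimate of the spread alone. The same holds for the 161 of orange peel powder against pectin without Avicel replicate 1 and sucrose replicate 1. The thresholds set their own shifts, and the cause of the others was not tested. Other counts stayed within 1.5 times the reported ones, including the 158 shared genes (130 to 161 without 1 replicate).

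The replicate numbers do not pair the libraries: of 26 same-numbered pairs 9 had deviations from the group means correlated above 0.1 (range -0.31 to 0.45), and 4 of 14 libraries correlated best with their own number. With the block no count except the 15 moved by more than 1.5 times, 2 list calls were gained and 1 was lost, and 4 calls of named genes were lost. Of 99 list tests, 36 calls were lost with an estimated correlation. Without Avicel replicate 1 and sucrose replicate 1, 4 list calls with the preset correlation were lost and 1 was gained, and 16 of the 29 calls with an estimated correlation were lost. In the same fits the cellulose-degradation list no longer passed in pectin against no carbon (adjusted p = 0.0628 with the preset correlation, with 0.0350 in the reported fit and 0.488 with an estimated correlation). One direction turned among named genes: clr-2, called higher without carbon than on sucrose, had a log2 fold change of -0.40 under quantile normalization, and the cause was not tested. Calls of named genes were lost 18 times under quantile normalization, 2 under upper-quartile scaling, 9 with a pseudocount of 0.1, 9 with the floor and 116 in fits without 1 replicate. For the xylan library 4 list medians moved by more than the spread of the compared libraries with a pseudocount of 0.1 and 9 under upper-quartile scaling. Low values are least precise in Avicel replicate 1, sucrose replicate 1 and the xylan library, and the depth of the 6 new libraries is unknown.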

Other observations

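The families by gene symbol, the test of galacturonate-use genes in the xylan library, the test of conidiation markers on Avicel, the ratio of counts as reported and the regrouping of libraries were chosen after the results were seen.

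Genes with arg and cys symbols were mostly lower than on sucrose in the 4 replicated groups compared with it. Among 39 families of at least 6 genes that share a symbol, 9 of 11 arg genes (arginine synthesis) were lower without carbon, on Avicel, on pectin and on orange peel powder, with median log2 fold changes of -4.62, -3.81, -2.79 and -3.07. Of 10 cys genes (sulfur amino acid synthesis), 9, 10, 9 and 9 were lower, with medians of -2.20, -2.71, -1.78 and -1.68. Neither family passed with an estimated correlation (adjusted p of 0.0861, 0.0718, 0.0589 and 0.0649 for both). These medians kept their sign under upper-quartile and quantile scaling. The isoleucine and valine synthesis gene ilv-2 was at 15993 ± 3487 FPKM on sucrose (SD, n = 3), 71.0 ± 7.89 without carbon (n = 3), 132 ± 88.9 on Avicel (n = 3), 277 ± 132 on pectin (n = 3) and 414 ± 73.8 on orange peel powder (n = 2), and at 6332 in the xylan library, far above those 4 groups. All 8 measured crp genes, which encode cytoplasmic ribosomal proteins, were lower than on sucrose in the same 4 comparisons (adjusted p of 0.465, 0.419, 0.671 and 0.564 with an estimated correlation), though with quantile normalization 1 of 8 was called on pectin and 1 on orange peel powder.

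Pectin-degradation and galacturonate-use genes were higher on pectin than without carbon, and a difference between the sources of the libraries is a candidate explanation beside the carbon source. The xylan library, of the new source, lay at a median of -2.61 from the pectin mean over the pectin-degradation list and 2.49 above no carbon. The first value is past the bound of -1 set in advance against the source, but that bound was wrong for this design, because a single library on another polysaccharide excludes nothing, so source and carbon source cannot be told apart. Over the galacturonate-use list the xylan library lay at -0.94 from the pectin mean and 4.59 above no carbon. The first value is within the bound of -1, but it was -1.05, past the bound, with upper-quartile scaling. These genes were thus high in all 3 carbon sources of the new source. Both a difference between sources and a response to the carbon source allow this, and here too a single xylan library cannot tell them apart. Pectin as the cause stays open for both lists and was not tested apart from the source.

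Conidiation markers were lower on pectin and orange peel powder than without carbon. The xylan library, of the same source, lay at -3.54 from the no-carbon mean, which is consistent with a difference between sources and also with a response to any added polysaccharide. A high marker level confined to starved mycelia may also account for the pattern: within the earlier source the markers on Avicel gave an adjusted p of 0.177 with an estimated correlation, which leaves it open, while against sucrose the median was 7.20 on Avicel and 9.34 without carbon, with all 7 markers higher in both (adjusted p of 0.141 and 0.198 with an estimated correlation). The shake-flask cultures were started from conidia, and the share of conidia or aerial hyphae in each harvest was not measured here.

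More genes were called against no carbon for pectin than for Avicel, by a ratio of 3.34. The ratio did not fall without the shallow Avicel replicate 1 and sucrose replicate 1, where it was 3.60. That fit has fewer Avicel than pectin libraries, which itself favors the pectin count. The depth of the pectin libraries is also unknown, so an effect of depth on the ratio stays open. With only the compared groups in each fit the counts were 2184 and 332, so the ratio depends on the fit. Pectin libraries came from another source than the no-carbon libraries and Avicel libraries did not, so an effect of the source on the count may add to it and cannot be told apart from the carbon source. A stronger response to pectin was not tested.

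The 6 libraries of each comparison between groups of 3 were also regrouped in all 10 ways, and 1 of 10, the real grouping, gave as many called genes each time. The highest other counts were 2 against 554 for Avicel and no carbon, 32 against 4232 for Avicel and sucrose, 0 against 4547 for no carbon and sucrose, 0 against 1848 and 0 against 3552 for pectin against no carbon and sucrose, and 1 against 1385 for pectin and Avicel. Each other grouping puts libraries of both conditions into each group, so their real differences widen the spread within groups. Low counts there were set in advance and do not measure what chance would give. With 10 groupings a share under 0.05 cannot be reached.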
